A study of Mus musculus with 2 samples.

How the data were processed

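The series holds ATAC-seq of mouse neural tube at embryonic day 12.5, from 2 pools of embryos that the labels number as biological replicates. Per the labels, chromatin was tagged with Nextera transposase and the size range was 200 to 750 bp. The aligner, the peak caller, any shift of reads for the transposase and any filter on problem regions are not given in the sources used here. Per the file headers and the deposited file lists, the coordinates are on mm10. The authors deposited peak lists for each replicate (IDR ranked, IDR thresholded and pseudoreplicated) and for the series (ranked, thresholded, conservative thresholded, replicated and pseudoreplicated), 12 lists in all.

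Each row of a deposited list is 1 summit, and an interval is repeated once per summit. The authors' column of peak height is a fold enrichment, a linear ratio. The authors' p and q columns are on the −log10 scale. The IDR of the ranked lists is deposited as a −log10 score. These values belong to the authors and were used only to describe, rank or filter peaks within 1 list. On the files it was tested that every summit of a thresholded list passes an IDR of 0.05 in its ranked list. The files give no read counts, so the depth of each replicate is unknown. Intervals on shares cover counting error only.

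Intervals on chromosomes 1 to 19, X and Y that overlapped were merged into regions, each with the summit of highest signal. Of 1109928 such rows, 0 ended past the end of a chromosome of GRCm38. Genes and TSSs came from GENCODE release M21 on the same build, and sequence from GRCm38. A promoter region has its summit within 1000 bp of a TSS of a protein-coding gene, and all other regions are distal. A promoter was called open when a region came within 500 bp of any annotated TSS. Distal regions were assigned to the nearest protein-coding TSS, and a gene's territory is the sequence nearest to its TSSs. Gene tests kept 1 entry per gene symbol, so a few promoter regions of a repeated symbol counted as distal there.

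The main values came from the conservative list and the replicate values from each replicate's IDR-thresholded list. Overlap meant 1 bp or more, and random placement was repeated 20 times. The 21 gene lists, 22 motif strings, tests and the rule for named genes were fixed before the data were examined. Genes were named by this rule: the 3 genes of each list with the most distal regions and up to 4 members without an open promoter, the 10 genes with the most distal regions, the genes nearest to the 10 highest-signal regions, the genes nearest to the 5 highest-signal regions of each replicate absent from the other's least strict list, and Hox genes by cluster. Further genes named as examples of what a list holds (Pax6, Tubb3, Dcx) come from the fixed lists. Open promoters were tested with Fisher's exact test. Distal counts were tested against 10000 random lists matched by decile of territory length, motifs with Fisher's exact test against windows that overlap no region of the tested list or of the pseudoreplicated list of the series, and recurrence with Fisher's exact test. Odds ratios from these tables had 0.5 added to each cell, and the direction of a motif or recurrence value was read from the shares without it. All p-values were two-sided and adjusted with Benjamini-Hochberg within a family. Genes, regions and motifs are not biological replicates, so these tests describe the lists and each replicate was tested on its own too. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6, numba 0.67.0 and matplotlib 3.10.9 were used, with a fixed seed.

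The code was tested on simulated data. A 20-gene list with 95% open promoters was called in 83.0% of simulations over 21911 genes, one with 20% open in 53.0%, and 0.474% of unchanged lists were called. For distal counts, 3 simulation designs were run one after another because the first ones recovered few lists, with the test unchanged throughout, and the recovery depended on the design. A 20-gene list at 2 times its rate was called in 0, 6.67% and 13.3% of simulations. At 3 times its rate it was called in 0 of the simulations that drew regions by territory length with strong skew, in 6.67% with milder skew and longer territories, and in 63.3% when the real counts were permuted within territory deciles. At 5 times the rate the shares were 30%, 63.3% and 80%. At most 0.333% of unchanged lists were called in any design. Because recovery at 2 to 3 times the rate was low in most designs, a list that is not called is weak evidence of no excess. For motifs, all 22 were recovered when written into 5% of windows, and 0 were called with nothing written in. Both window sets were random genome sequence, so this could not show false calls that come from a difference in GC content. Recovery was scored without the odds ratio of at least 1.5 in both replicates that the real calls needed. Some strings matched far fewer than 5% of the real distal summits, such as NFI at 0.122%, and recovery at such rates was not simulated. The HNF1 string had no match at these summits or in their flanks, so it could not be called. The overlap code differed from a direct comparison in 0 of 4077 cases.

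Alternatives covered the overlap rule, the promoter window, the choice of TSS, the background, the peak list, a stricter signal threshold, the assignment of distal regions, the motif window and background, and leaving out each replicate. Stratification by promoter CpG content, with a Mantel-Haenszel odds ratio, and matching on territory GC content were added after the files had been seen and before any gene list was tested. The GC matching used quintiles of territory length and of GC content, so length was matched more coarsely than in the main test. Added after the results were seen were 45 gene families defined by symbol and the count of 31-bp words shared with other sequence. The input-specific p-values of the ranked lists were not used, because no label names the replicate they belong to.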

Results

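Open chromatin of the embryonic mouse neural tube, the tissue that forms the spinal cord and brain, was measured at embryonic day 12.5 with ATAC-seq, in which a transposase cuts and tags accessible DNA. There was 1 group of 2 biological replicates. Replicate 1 pooled tissue from 120 embryos and replicate 2 pooled tissue from 88 embryos of the B6NCrl strain, with both sexes mixed. The deposited files are peak lists on the mouse build mm10 (GRCm38), called for each replicate and for the series. They give no read counts, so sequencing depth was unknown and no difference between the replicates was scaled to it. With 1 group the labels imply a comparison of replicate with replicate and a description of where the open regions lie, and no test between conditions was possible. The conservative list of the series, thresholded on the irreproducible discovery rate (IDR), held 70090 summits in 23824 distinct regions with a median width of 1061 bp. These regions covered 25.0 Mb, or 0.919% of the genome.

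Strong regions were found in both pools of embryos, and the regions that were not shared were mostly weak and distal. Replicate 1 had 15404 IDR-thresholded regions and replicate 2 had 18253, a mean of 16829 ± 2015 (SD, n = 2). Of the replicate 1 regions, 91.3% (95% Wilson interval 90.8 to 91.7) overlapped a replicate 2 region by at least 1 bp, and 76.4% (75.8 to 77.0) of the replicate 2 regions overlapped a replicate 1 region. Regions placed at random anywhere on their own chromosome gave 1.47% and 1.23%. The placement ignored promoters, where most regions of both replicates lay, so it makes a low baseline. Among promoter regions the shares were 95.9% and 89.9%, and among distal regions, over 1 kb from every transcription start site (TSS) of a protein-coding gene, they were 81.5% and 55.5%. With the same number of top-ranked regions from each replicate, the shares were 82.6% and 81.7%. Against the other replicate's less strict pseudoreplicated list, 99.6% and 98.1% of the regions had an overlap. With the replicate 2 regions split by signal into 5 bins of equal size, 49.2% of the weakest bin and 99.4% of the strongest overlapped replicate 1.

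**Figure D1:**
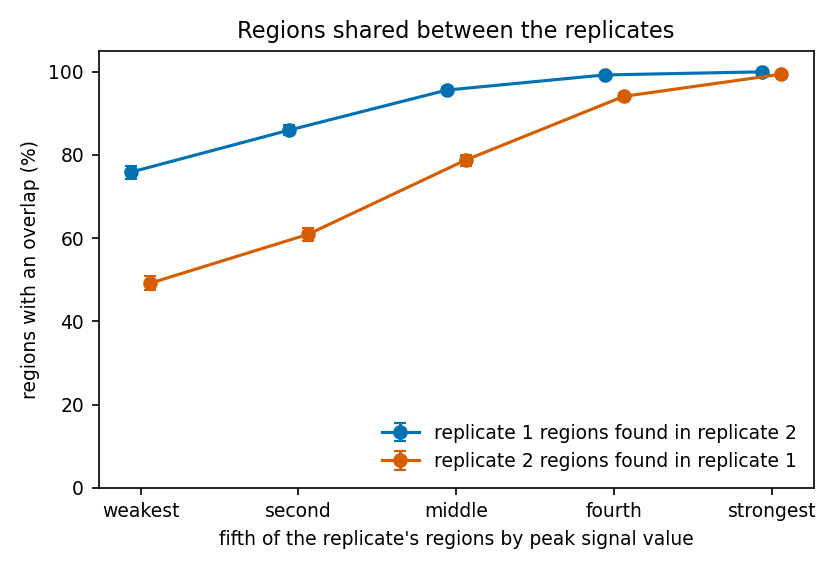
Share of each replicate's IDR-thresholded regions (percent, y axis) that overlap a region of the other replicate, by peak signal value within the replicate in 5 bins of equal size (x axis), with 95% Wilson intervals covering counting error only. The share goes from 75.9% to 99.9% for replicate 1 and from 49.2% to 99.4% for replicate 2.

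The order of the shared regions by signal was also close. Across 14062 pairs of overlapping regions the authors' signal values had a Spearman rho of 0.874 (95% bootstrap interval 0.869 to 0.879). This is a correlation across regions, which are not independent replicates. Rho was 0.891 across promoter regions and 0.758 across distal regions. The summits of overlapping regions lay a median of 15 bp apart.

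Promoters held more than their share of the open regions. Of the conservative regions, 51.9% had their summit within 1 kb of the TSS of a protein-coding gene, which makes up 3.59% of the genome, a 14.4-fold excess. Introns held 18.8% of the regions, exons 1.97% and intergenic sequence 27.3%, against 32.7%, 2.57% and 61.2% of the genome. Within the replicates the promoter share was 64.4% ± 5.08 (SD, n = 2). It depended on the strictness of the list: the less strict replicated list of the series gave 28.8% and the conservative regions above the median signal gave 71.2%. With TSSs of all annotated genes counted, the promoter share was 56.2%. Some regions called distal here therefore lay within 1 kb of a TSS of a gene outside the protein-coding set. In the decile of regions with the highest signal 90.4% were promoters, while the lowest share, 27.4%, was in the second decile from the bottom.

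Promoters of neural progenitor, pan-neuronal and housekeeping genes were open more often than those of other protein-coding genes, and promoters of blood, endothelial, liver, germline and chemosensory receptor genes less often. Of 21911 protein-coding genes, 12445 (56.8%) had a conservative region within 500 bp of a TSS, and in the replicates the share was 51.1% ± 1.74 (SD, n = 2). Among 20 neural progenitor genes, which include the stem cell regulators Sox2, Pax6 and Hes1, 19 had an open promoter (adjusted exact p = 0.00146, Fisher's exact test, two-sided, Benjamini-Hochberg over 21 lists). Of 28 pan-neuronal genes, which include neuronal cytoskeleton genes such as Tubb3 and Dcx, 26 were open (adjusted exact p = 0.000313), and of 20 housekeeping genes all 20 were (adjusted exact p = 0.000103). On the other side stood blood and microglia genes with 3 of 18 open (adjusted exact p = 0.00212), endothelium and pericyte genes with 4 of 16 (adjusted exact p = 0.0308), liver and gut endoderm genes with 1 of 17 (adjusted exact p = 0.000103), pluripotency and germline genes with 1 of 12 (adjusted exact p = 0.00212) and chemosensory receptor genes with 4 of 1475. All 8 of these lists were called in the same direction in each replicate's own list. With genes stratified by promoter CpG content, a setting added after the files had been seen, the neural progenitor (odds ratio 4.29), blood (0.600) and endothelium (0.314) lists no longer passed, nor did the housekeeping list, which has no finite odds ratio because every member was open. The endothelium call was also lost with a promoter window of 1 kb (adjusted exact p = 0.0894) or 100 bp (adjusted exact p = 0.0530) and in the replicated list (adjusted exact p = 0.165). Among regions above the median signal the direction turned for the neural progenitor list, with 35% open (odds ratio 0.750), and the pan-neuronal list, with 25% open (0.470).

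The lists of dorsoventral progenitor domain and spinal neuron subtype genes were not called in the conservative list. Of 30 dorsoventral progenitor domain genes, 13 had an open promoter (adjusted exact p = 0.189), and of 40 spinal neuron subtype genes 21 did (adjusted exact p = 0.633). Members without one included Dbx1 and Dbx2, which mark interneuron progenitors, Foxa2, a floor plate factor, and Foxn4. In the spinal neuron list they included Barhl1, Chat, which makes acetylcholine in motor neurons, Dmrt3 and En1. The forebrain and midbrain list had 8 of 24 open (adjusted exact p = 0.0545), with Dlx5, Emx1, Emx2 and Eomes among those that were not. The Notch signalling list had 12 of 14 (adjusted exact p = 0.0656), and the Sonic hedgehog list 10 of 12 (adjusted exact p = 0.142), with Shh and Gli1 the exceptions. The forebrain and midbrain list was called lower with the 5' end of each gene as its only TSS (adjusted exact p = 0.00673) and without chemosensory genes in the background (adjusted exact p = 0.0257). Notch was called higher in the replicated list (adjusted exact p = 0.0479) and Sonic hedgehog with a 1 kb window (adjusted exact p = 0.0461). The glial list had 6 of 16 open (adjusted exact p = 0.189), the neural crest list 11 of 22 (adjusted exact p = 0.582), the somite, muscle and cartilage list 9 of 23 (adjusted exact p = 0.154), the Wnt and BMP list 8 of 17 (adjusted exact p = 0.546) and the retinoic acid list 4 of 10 (adjusted exact p = 0.427), or 1 of 10 with the 5' end only (adjusted exact p = 0.0183). In the less strict replicated list of the series, 87.5% of the spinal neuron promoters and 73.3% of the dorsoventral promoters had a region, and the spinal neuron list was called higher there (odds ratio 3.60, adjusted exact p = 0.00435). In replicate 1's own list 4 lists were called lower: dorsoventral, with 7 of 30 open (adjusted exact p = 0.0136), glial (adjusted exact p = 0.0395), forebrain and midbrain (adjusted exact p = 0.0395) and somite (adjusted exact p = 0.00776). With genes stratified by promoter CpG content 7 lists with an odds ratio under 1 in the conservative list were called lower: the dorsoventral (odds ratio 0.113), spinal neuron (0.350), Hox 10-13 (0.108), forebrain and midbrain (0.135), neural crest (0.373), somite (0.297) and Wnt and BMP (0.189) lists.

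**Figure D2:**
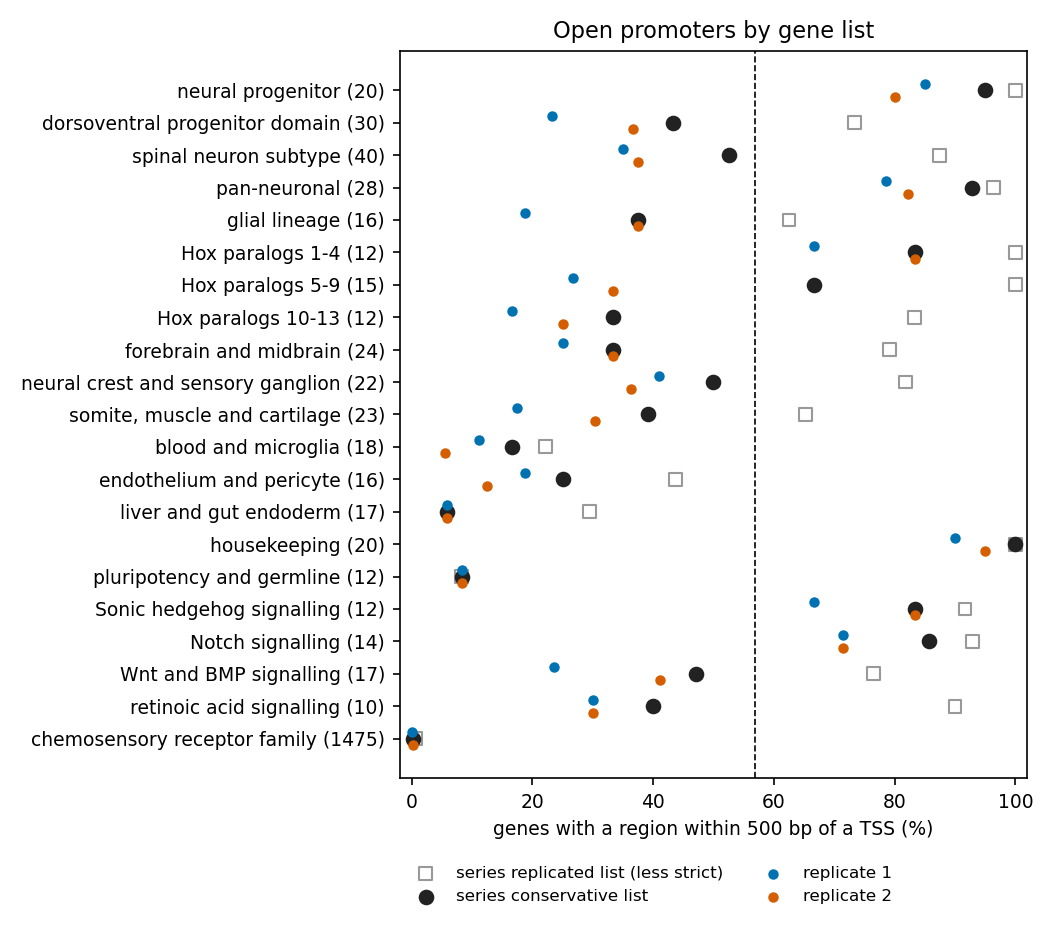
Percent of the genes of each fixed list (number of genes in brackets, y axis) with a region within 500 bp of a TSS (x axis), in the conservative list, the replicated list and each replicate. The dashed line marks 56.8%, the share of all protein-coding genes in the conservative list; the housekeeping list reaches 100% and the chemosensory receptor list 0.271%.

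Distal regions were more numerous than expected around the genes of 9 lists, which did not include the forebrain and midbrain, Sonic hedgehog and retinoic acid lists. Some lists share genes, so these calls are not independent. For example, Hes1 and Notch1, with 8 and 6 distal regions, were in both the neural progenitor and the Notch lists. The conservative list had 11457 distal regions, assigned to the gene with the nearest TSS, and 5504 genes had at least 1. Neural progenitor genes had a mean of 3.70 distal regions each, 3.64 times the mean of random gene lists matched by territory length (adjusted permutation p = 0.00210, permutation test with 10000 random lists, two-sided). The replicates gave 3.74 ± 0.288 times (SD, n = 2). Notch signalling genes had 4.04 times the expected number (adjusted permutation p = 0.00420), Wnt and BMP signalling genes 2.80 times (adjusted permutation p = 0.00480), glial genes 2.61 times (adjusted permutation p = 0.0193), pan-neuronal genes 2.35 times (adjusted permutation p = 0.00480), dorsoventral genes 2.28 times (adjusted permutation p = 0.00420) and spinal neuron genes 1.78 times (adjusted permutation p = 0.0191). In the glial list Nfib and Nfia held 9 and 8 distal regions, the median was 1, and 11 of the 16 genes had any. The Hox paralogs 1-4 and 5-9 had 7.19 and 6.73 times the expected number (adjusted permutation p = 0.00480 and 0.0152), on means of 1.08 and 0.333 regions per gene. Hoxc4 held 7 of the 13 regions of paralogs 1-4. The ratio of paralogs 5-9 was 11.3 in replicate 1 and 4.30 in replicate 2. That of paralogs 1-4 was 3.89 in the replicated list. With random lists not matched by territory the Hox ratios were 2.08 and 0.631 and neither was called. Chemosensory receptor genes had 0.177 times the expected number (adjusted permutation p = 0.00210). Against random lists matched on quintiles of territory length and of GC content they had 0.446 times (adjusted permutation p = 0.00140). The length matching was coarser there, so the change cannot be assigned to GC content alone. The spinal neuron list was not called in either replicate's own list (adjusted permutation p = 0.260 in replicate 1 and 0.377 in replicate 2), the glial and the Wnt and BMP lists were not called in replicate 1 (adjusted permutation p = 0.0863 and 0.0840), and the Hox paralogs 5-9 were not called in replicate 2 (adjusted permutation p = 0.344). In the replicated list the Notch ratio was 2.497 and the Wnt and BMP ratio 1.79, which was not called (adjusted permutation p = 0.0664). Beyond 5 kb from every protein-coding TSS the spinal neuron (1.43 times, adjusted permutation p = 0.259), Wnt and BMP (2.08, adjusted permutation p = 0.117), Hox 1-4 (4.81, adjusted permutation p = 0.0564) and Hox 5-9 (3.39, adjusted permutation p = 0.656) lists were not called, and above the median signal only the neural progenitor list was called higher (3.37 times).

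The remaining lists did not pass this test. The somite, muscle and cartilage list stood at 1.00 times the expected number (adjusted permutation p = 1), the endothelium list at 0.974 (adjusted permutation p = 1), the neural crest list at 1.22 (adjusted permutation p = 0.646; 2.60 and called against unmatched random lists, adjusted permutation p = 0.0441), the forebrain and midbrain list at 1.24 (adjusted permutation p = 0.635) and the pluripotency list at 1.26 (adjusted permutation p = 0.726). Blood and microglia genes stood at 2.26 (adjusted permutation p = 0.135), liver genes at 2.01 (adjusted permutation p = 0.278; 0.570 in replicate 1 and 2.05 in replicate 2), housekeeping genes at 1.96 (adjusted permutation p = 0.278), Sonic hedgehog genes at 2.02 (adjusted permutation p = 0.111) and retinoic acid genes at 1.78 (adjusted permutation p = 0.278). The blood ratio was 1.17 in the replicated list. That of the pluripotency list was 1.65 in replicate 1 and 2.01 in replicate 2. The Sonic hedgehog list passed with regions within 100 kb of the TSS (2.74 times, adjusted permutation p = 0.0225), with all regions within 50 kb (2.78 times, adjusted permutation p = 0.0113) and against unmatched random lists (4.81 times, adjusted permutation p = 0.00210). The Hox paralogs 10-13 had no distal region (adjusted permutation p = 0.665).

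**Figure D3:**
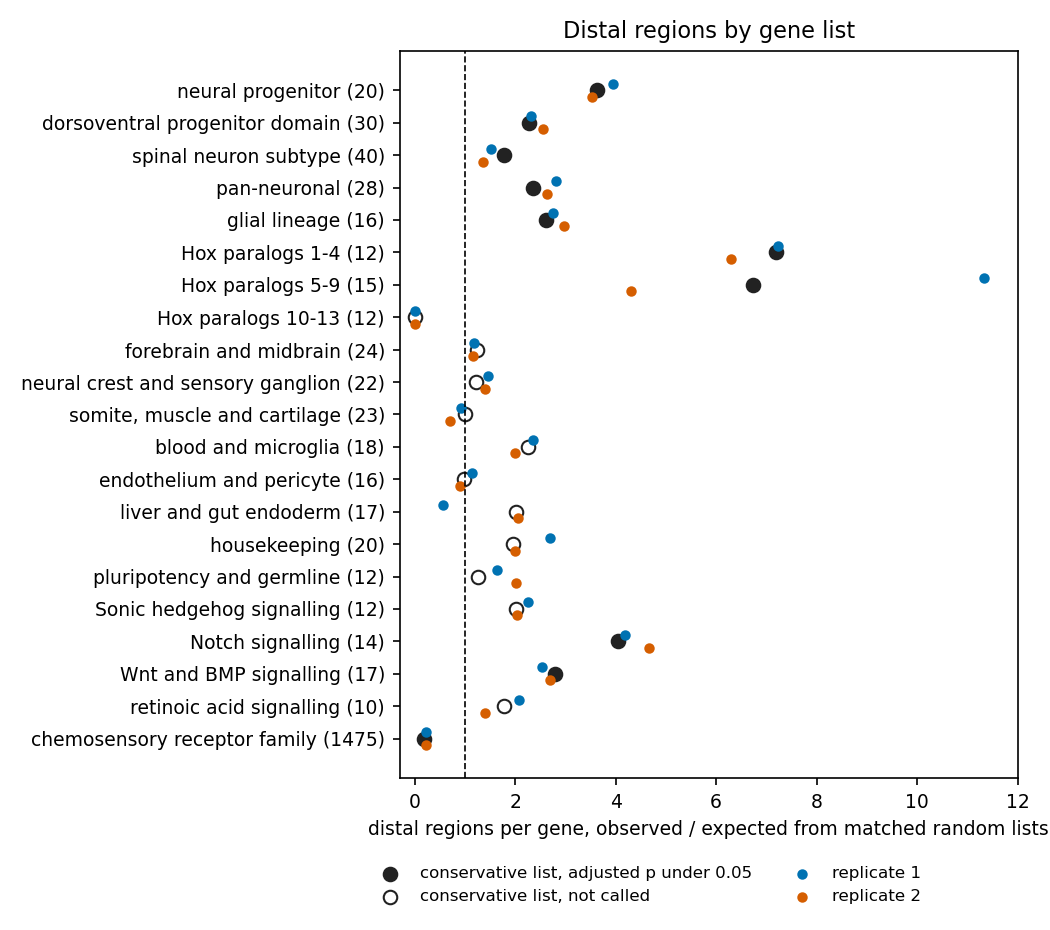
Distal regions per gene of each fixed list (number of genes in brackets, y axis), as the ratio of the observed mean to the mean of random lists matched by territory length (x axis), in the conservative list and in each replicate. Filled black points passed the permutation test in the conservative list; the neural progenitor list stands at 3.64 and the chemosensory receptor list at 0.177.

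Sox9, a factor of neural stem cells and glia on chromosome 11 (112782224 to 112787760), had 14 distal regions in the conservative list, 7 in replicate 1 and 10 in replicate 2. The one with the highest signal lay in intergenic sequence on chromosome 11 with its summit at 112502026, 280198 bp from the nearest Sox9 TSS. Sox2, on chromosome 3 (34650405 to 34652461), had 12 distal regions, with 4 and 3 in the replicates. Its highest-signal one was intergenic, with its summit at 35088618 on chromosome 3, and 438213 bp from the TSS. Pax3, a factor of the dorsal neural tube, had 10 (4 and 6 in the replicates), and Ascl1, a proneural factor, had 7 (3 and 5). The highest-signal distal region of Ascl1 had its summit at 87447861 on chromosome 10, 45799 bp from the TSS in intergenic sequence. Myt1l, a neuronal zinc finger factor, had 12 distal regions (8 and 10), and its promoter was open in the conservative and the replicated list but in neither replicate's own list. Hes1, an effector of Notch on chromosome 16 (30064384 to 30067796), had 8 (2 and 3), Jag1, a Notch ligand, had 7 (2 and 6), and the hedgehog effector Gli3 had 7 (2 and 3). In the glial list Nfib had 9 (6 and 9) and Nfia 8 (4 and 6), with the highest-signal ones in their own introns. Genome-wide the genes with the most distal regions were Celf4 and Gm11146 with 20 each, Gse1 with 18, Nrxn3 and Pou3f3 with 17, Nr2f1 and Tmem161b with 16, and Auts2, Maml3 and Mef2c with 15. In replicates 1 and 2 the counts and their order differed, with 12 and 11 for Celf4, 11 and 16 for Gm11146, 5 and 6 for Gse1, 6 and 11 for Nrxn3, 8 and 15 for Pou3f3, 4 and 12 for Nr2f1, 14 and 16 for Tmem161b, 4 and 7 for Auts2, 10 and 12 for Maml3, and 13 and 12 for Mef2c. Among genes of other tissues Ptprc, a leukocyte surface protein, had 9 distal regions (6 and 6) and no open promoter in any of the lists used. Assignment to the nearest TSS does not show that a region acts on that gene.

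Within the Hox clusters, whose genes set position along the body axis, open promoters in the conservative list were most frequent among the low paralog numbers. There, 10 of 12 genes of paralogs 1-4, 10 of 15 of paralogs 5-9 and 4 of 12 of paralogs 10-13 had an open promoter, and none of the 3 lists differed from other genes by the exact test (adjusted exact p = 0.142, 0.633 and 0.189). Paralogs 1-4 and 5-9 were called higher in the replicated list (adjusted exact p = 0.0125 and 0.00500) and lower above the median signal, where none of their promoters was open (adjusted exact p = 0.00391 and 0.00127) while 2 of the 12 paralogs 10-13 were, so the order did not hold there. The trend across the 3 lists was not tested. A promoter counted as open at any annotated TSS, and some Hox genes have annotated spans that overlap others. On chromosome 2 Hoxd3 and Hoxd4 are annotated from 74711927 and 74711929, so a region can count for more than 1 gene. The HoxA cluster on chromosome 6 (52155590 to 52260880) had 7 of 11 promoters open, HoxB on chromosome 11 had 5 of 10, HoxC on chromosome 15 had 6 of 9 and HoxD on chromosome 2 had 6 of 9. In the replicates 30% ± 4.71 of the paralogs 5-9 had an open promoter (SD, n = 2), while in the replicated list all 15 did. In that list the genes without a region were Hoxc12 and Hoxd12.

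The 10 regions with the highest signal lay mostly outside promoters, while of the 100 with the highest signal only 22 were distal. Of the 10, 9 were distal, all 10 were found in both replicates, and their median width was 390.5 bp. The first was on chromosome X (143482934 to 143483180), in intergenic sequence 35531 bp from a TSS of Pak3, with a fold enrichment of 56.01. The next lay on chromosome 2, near Abcb11 (69355470 to 69355735) and Frmd4a (3964426 to 3964690). The others lay nearest to Gm5426, G6pd2, Galc, 4930467E23Rik, Cldn34d, Tyrp1 and Zfp960. In 5 of these 10 regions over 10% of the 31-bp words were also present in the mitochondrial genome, against 0 of 500 randomly drawn distal regions. In 3 of the 10 most of the words occurred more than once in the nuclear genome, against 2.40% of the drawn distal regions. Among the regions of 1 replicate with no overlap in the other's least strict list, those with the highest signal lay nearest to Atxn10, Epm2a, Otud3, Myf5 and Pkdcc in replicate 1, and to Nr5a2, 4932438H23Rik, Cited2, Scn8a and Kif18b in replicate 2.

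Distal summits carried matches to the motifs of CTCF and RFX and to 2 bHLH strings more often than their flanks, and 1 of the 2 bHLH strings reached the odds ratio required. Windows of 201 bp at 11457 distal summits were compared with 20362 windows centred 1 kb away. Of 22 fixed consensus strings, 10 were enriched, each with an odds ratio of at least 1.5 in both replicates, and the largest adjusted p among them was 0.000192 (Fisher's exact test, two-sided). CTCF, which binds insulators, matched 5.22% of summits and 0.103% of flanks, an odds ratio of 52.1 (23.4 in replicate 1 and 49.5 in replicate 2). The RFX X-box, bound by factors of ciliated and neural cells, matched 73 summits and 0 flanks. The E-box CAGCTG, bound by factors such as ASCL1, matched 25.3% of summits and 8.91% of flanks, an odds ratio of 3.47 (3.67 ± 0.00417, SD, n = 2). The POU octamer (odds ratio 2.56), the HOX-PBX site (2.03), NFY (1.63), ETS (3.24), SP/KLF (6.24), NRF1 (12.5) and NFI (7.37) were enriched too, NFI on 14 summit matches and with adjusted exact p = 0.423 in replicate 1. In replicates 1 and 2 the odds ratios were 6.33 and 4.49 for ETS, 10.3 and 7.83 for SP/KLF, 10.0 and 6.07 for NRF1, and 2.22 and 5.28 for NFI. The NFY call was lost with flanks 5 kb away (1.41) and in the replicated list (1.28). GATA was less frequent at summits than in flanks (odds ratio 0.477), and the E-box CAGATG of NEUROG and ATOH1 (1.46), SOX (1.35) and TAAT homeodomain (1.03) sites did not reach the odds ratio required. EBF (1.86) missed it in replicate 1 (1.46). It was called with narrower windows, with flanks 5 kb away and without replicate 1. Its string read backwards was called too (2.21), and with flanks matched by GC content its odds ratio was 1.07.

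The motif calls depended on base composition. Summit windows had a GC content of 53.9% and flanks 44.4%. With 8164 windows on each side matched by GC content, 7 of the 10 motifs kept their call. Among these the E-box CAGCTG odds ratio went from 3.47 to 2.11, the POU octamer from 2.56 to 4.91, HOX-PBX from 2.03 to 4.03 and CTCF from 52.1 to 31.4. ETS (odds ratio 1.04), NRF1 (2.60, adjusted exact p = 0.353) and SP/KLF (1.48) did not, while SOX (2.09), TAAT homeodomain (3.10) and posterior HOX or CDX sites (1.98) were now called.

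**Figure D4:**
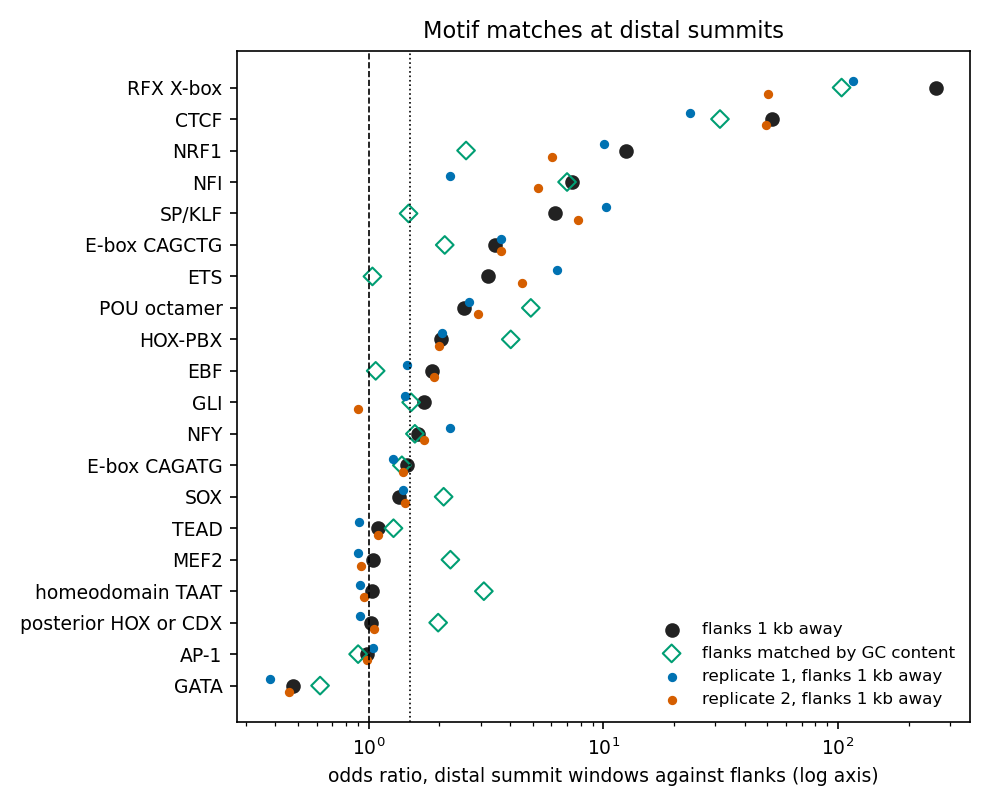
Odds ratio of a motif match in 201-bp windows at distal summits against flanking windows (log x axis), for each fixed motif with at least 10 matches (y axis). Black points use flanks 1 kb away, diamonds flanks matched by GC content, and small points each replicate; the dotted line marks 1.5, and CTCF stands at 52.1 with flanks 1 kb away and 31.4 with matched flanks.

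Regions near genes of the dorsoventral list recurred less often than other regions of replicate 2. Of 62 such regions 51.6% overlapped replicate 1, against 76.5% of all others (odds ratio 0.327, adjusted exact p = 0.000569, Fisher's exact test), and of 15 regions near somite, muscle and cartilage genes 40.0% did (odds ratio 0.211, adjusted exact p = 0.0270). No list passed the test in replicate 1, where the smallest adjusted p was 0.101 and 6 lists had an unadjusted p under 0.05. These shares are not adjusted for signal, and weak and distal regions recurred less often. Both calls were lost against replicate 1's less strict list, which all 15 somite regions overlapped. For the dorsoventral list the odds ratio there was 0.326, with 95.2% of its regions and 98.1% of all others overlapping.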

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

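The tests of promoter CpG content on single lists, the split by promoter and distal class and the comparison of regions without an overlap in the other direction were chosen after the result was seen, and CpG stratification and GC matching were added after the files had been seen. Some summits passed the IDR limit of a ranked list and were absent from the thresholded list made from it, and no comparison used them. There were 208 in replicate 1, 185 in replicate 2, 264 for the conservative list and 259 for the other thresholded list of the series. The 264 included 99 on unplaced scaffolds, and the rest formed 61 regions. Of these, 22 consisted mostly of 31-bp words found more than once in the genome, and 1, on chromosome 1 (24611587 to 24616165), shared 98.8% of its words with the mitochondrial genome.

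The blood, endothelium, liver, pluripotency and chemosensory lists had fewer open promoters and 3 lists had more, and promoter CpG content was weighed as an explanation. With genes stratified by CpG decile, 3 of the 5 lists with fewer open promoters were still called. This share fell between the bounds set before the test, so it does not decide on CpG content for the 5 lists together. In the 3, the liver, pluripotency and chemosensory lists, singled out after the result, a difference remained within CpG deciles. CpG content was taken around the 5' end of each gene, while a promoter could be open at any TSS, so other TSSs were not adjusted for. The blood odds ratio went from 0.172 (95% interval 0.0538 to 0.547) to 0.600 (0.109 to 3.29), and that of the endothelium list from 0.274 (0.0931 to 0.804) to 0.314 (0.0838 to 1.18); the first moved toward 1 and the second ended its call mainly by a wider interval, so CpG content stays open for both. Of the 3 lists with more open promoters 1 was still called, the pan-neuronal list with 39.6 (5.73 to 274.6), while the neural progenitor list went from 9.90 (1.88 to 52.1) to 4.29 (0.711 to 25.9) and the housekeeping list had no closed member to compare. The share still called again fell between the bounds set before the test. No biological explanation was tested, since the design has 1 group.

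The excess of distal regions near the genes of 9 lists, some of which share genes, was weighed against territory GC content and against a general richness of regulator genes. Of the 9 lists called, 6 were still called when random lists were matched on quintiles of both territory length and GC content. This share fell between the bounds set before the test, so it does not decide on GC content for the 9 lists together. The spinal neuron list went from 1.78 to 1.61 times (adjusted permutation p = 0.0588). The Hox 5-9 list went from 6.73 to 4.21 (adjusted permutation p = 0.0588) and the Wnt and BMP list from 2.80 to 1.82 (adjusted permutation p = 0.0909). The SD among matched random lists was 0.239, 0.978 and 0.343 for these 3. Length was matched in deciles in the main test and in quintiles here, so a changed ratio cannot be assigned to GC content alone. Transcription factors of the somite, blood, endothelium and liver lists (32 genes) had 1.17 times the expected number and those of the dorsoventral and spinal neuron lists (61 genes) 2.05 times, a ratio of 0.570 (permutation p = 0.0200), 0.398 and 0.453 in the replicates. This argues against an excess common to regulators of every tissue. The forebrain and midbrain list (1.24 times) and the neural crest list (1.22 times) were not part of the comparison, so it does not speak for neural regulators in general. That dorsoventral and spinal neuron regulators have more distal open regions in this tissue remains a hypothesis, since no other tissue was compared.

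Replicate 2 had 1.18 times as many regions as replicate 1. Of the 4301 replicate 2 regions without an overlap, 92.0% were in replicate 1's less strict list, over the 80% set before the test for fewer usable reads or weaker calling in replicate 1. In the other direction, compared after that result, it was 95.6% of 1342 regions, so the share does not set the replicates apart and this explanation stays open. Tissue carried along in a dissection stays open. The genes of other tissues were here those of the somite, blood, endothelium, liver and neural crest lists. By the bound set before the test, an odds ratio under 0.8 with its interval under 1, regions near these genes recurred less often at a given signal in replicate 2 (0.494, 95% interval 0.295 to 0.828, 70 regions) and in replicate 1 (0.395, 0.205 to 0.762, 54 regions). Within promoter and distal classes, a split added after that result, the odds ratio kept to the bound in replicate 1 (0.492, 0.260 to 0.934) and not in replicate 2 (0.648, 0.387 to 1.09). Neural tube lists had 1.06 (0.802 to 1.39) in replicate 2 and 1.05 (0.696 to 1.57) in replicate 1 at a given signal, and within classes 1.38 (1.03 to 1.84) and 1.21 (0.8003 to 1.83).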

How the results depend on the processing

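The tests with CpG stratification and GC matching of territories were chosen after seeing the data. The overlap of replicate 1 and replicate 2 regions moved to 87.0% and 73.4% with 50% reciprocal overlap, 78.1% and 65.9% with summits within 100 bp, 84.5% and 69.7% with pseudoreplicated lists, 82.6% and 81.7% with equal numbers of regions, and 81.5% and 55.5% for distal regions. The rank correlation was 0.886 with matched summits, 0.907 with −log10 p values, 0.758 and 0.891 for distal and promoter regions and 0.821 with pseudoreplicated lists. The promoter share was 28.8% in the replicated list, 71.2% above the median signal, 56.2% with all genes in place of protein-coding genes, and 60.9% to 68.0% without either replicate. Lists with more open promoters numbered 7 in the replicated list, 1 above the median signal and 1 with CpG stratification, against 3; lists with fewer numbered 13 above the median signal, 10 with CpG stratification and 5 to 9 without either replicate, against 5. Lists rich in distal regions numbered 1 above the median signal, where there are fewer distal regions, and 5 beyond 5 kb from every protein-coding TSS, against 9; the 1 was the neural progenitor list (3.37), and beyond 5 kb the spinal neuron (1.43), Wnt and BMP (2.08), Hox 1-4 (4.81) and Hox 5-9 (3.39) lists were lost. Lists recurring less often in replicate 2 numbered 1 with reciprocal overlap, 0 against the less strict list and 1 above the median signal, against 2; the last was the chemosensory list (0.145), since the dorsoventral call was lost (0.460) and the somite list gave no value there. The somite odds ratio was 0.248 with reciprocal overlap, and the dorsoventral one 0.326 against the less strict list. Read backwards, 2 motifs were enriched, against 10. Of the 2, SP/KLF reads the same both ways and the other was EBF (2.21). Direction turned as follows, mostly without a call in either setting. The odds ratio of open promoters turned in the replicated list for the spinal neuron (3.60), dorsoventral (1.47), Hox 10-13 (2.34), forebrain and midbrain (1.97), neural crest (2.29), somite (1.01), Wnt and BMP (1.67) and retinoic acid (3.53) lists. Above the median signal it turned for the neural progenitor (0.750), pan-neuronal (0.470), Hox 1-4 (0.0539), Hox 5-9 (0.0435), Sonic hedgehog (0.715) and Notch (0.270) lists. In the other thresholded list it turned for Hox 5-9 (0.662), neural crest (1.07) and Wnt and BMP (1.05), which also turned with a 1 kb window (1.04). Hox 5-9 turned to 0.408 with CpG stratification and to 0.392 and 0.476 without either replicate. Distal ratios turned above the median signal for Hox 1-4 and Hox 5-9 (both 0), forebrain and midbrain (0.757), somite (0.738), endothelium (1.09) and housekeeping (0.864). With unmatched random lists they turned for Hox 5-9 (0.631), endothelium (1.43), liver (0.912) and housekeeping (0.765). The somite ratio, 1.00, went to 0.898 in the other thresholded list, 0.949 in the replicated list, 0.816 beyond 5 kb, and 0.709 and 0.922 without replicate 1 or 2. Endothelium turned without replicate 2 (1.14, and 0.902 without replicate 1), within 100 kb (1.04), with all regions within 50 kb (1.16) and beyond 5 kb (1.003), liver without replicate 2 (0.570, and 2.05 without replicate 1), pluripotency in the replicated list (0.837) and within 100 kb (0.958), and Hox 10-13 with all regions within 50 kb (1.97). Recurrence turned because every region of the list overlapped, in all but 1 case, so values under 1 in brackets come from the 0.5 added to each cell. Against the less strict list this held in replicate 1 for the neural progenitor (0.424), dorsoventral (0.299), spinal neuron (0.330), pan-neuronal (0.549), Hox 1-4 (0.113), Hox 5-9 (0.0659), forebrain and midbrain (0.144), neural crest (0.183), blood and endothelium (both 0.0815), Notch (0.237) and retinoic acid (0.0892) lists. In replicate 2 it held for neural progenitor (2.498), pan-neuronal (3.35), Hox 1-4 and somite (both 0.599), forebrain and midbrain (0.985), endothelium (0.405), liver (0.212), pluripotency (0.328), Sonic hedgehog and Wnt and BMP (both 1.22) and retinoic acid (0.483). Above the median signal it held in replicate 1 for neural progenitor (0.203), pan-neuronal (0.357) and neural crest (0.183), and in replicate 2 for spinal neuron (1.65), pan-neuronal (2.84), glial and Wnt and BMP (both 1.12) and Sonic hedgehog (0.856). The other case was Sonic hedgehog in replicate 1 with reciprocal overlap (0.716). Backwards strings gave 0.276 for the POU octamer, 0.571 for HOX-PBX, 0.779 for SOX, 0.874 for TAAT, 0.543 for CAGATG, 0.447 for posterior HOX or CDX, 0.404 for MEF2 and 0.483 for TEAD. Backwards strings of RFX, NFI, NRF1 and REST had no match and gave no value, and REST, which matched 1 summit and 4 flanks forwards, had none above the median signal. With 50 bp windows TAAT went to 0.837, posterior HOX or CDX to 0.959, AP-1 to 1.14 and MEF2 to 0.574. With flanks 5 kb away posterior HOX or CDX went to 0.934, MEF2 to 0.974 and REST to 1.94. AP-1 and REST went to 1.02 and 1.27 in the other thresholded list and 1.17 and 3.13 in the replicated list, where MEF2 went to 0.891. Above the median signal TAAT went to 0.891, posterior HOX or CDX to 0.860, and MEF2 to 0.610. Without replicate 1 TAAT went to 0.955, MEF2 to 0.931 and GLI to 0.899, with AP-1 at 0.987 and REST at 0.586, and without replicate 2 TAAT to 0.923, posterior HOX or CDX to 0.923, AP-1 to 1.04, MEF2 to 0.903, TEAD to 0.912 and REST to 5.18. Except where named, the cause was not tested. Counting all values of lists and motifs, 157 of 208 promoter odds ratios, 163 of 210 distal ratios, 64 of 100 recurrence odds ratios and 134 of 184 motif odds ratios kept both their direction and their side of the threshold. Of 760 counts of distal regions of named genes, 411 moved. Depth is unknown, so the absence of a region is not evidence of closed chromatin.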

Other observations

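The gene families in this part were defined by symbol after the main results were seen. Their tests were neither matched on territory GC content nor stratified by promoter CpG content. Among 45 such families, 9 had more distal regions than matched genes and 8 had more open promoters, by the same tests with adjustment over the families, while 2 had fewer distal regions (cytochrome P450, 0.440 times, and UDP glucuronosyltransferase, none) and 12 had fewer open promoters. Sox genes had 3.79 distal regions each, 3.15 times the expected number (adjusted p = 0.00720, permutation test; 3.56 and 2.84 in the replicates), Pax genes 3.19 times (adjusted p = 0.0180) and POU genes 2.73 times (adjusted p = 0.00750). The 4 nuclear factor I genes, which act in gliogenesis, had 5.75 each, 4.26 times the expected number (6.02 and 5.72 in the replicates). Most of these regions belonged to Nfib and Nfia of the glial list, with 9 and 8. Both had stood out in the main results before the family was defined. The proneural bHLH genes had 2.95 times (3.38 and 3.34 in the replicates). Among axon guidance families the ephrin and Eph genes had 2.53 times the expected number (adjusted permutation p = 0.00720) with 18 of 22 promoters open, and the netrin, Slit and Robo genes 2.12 times (adjusted p = 0.0369). Of 29 semaphorin and plexin genes 25 had an open promoter (adjusted exact p = 0.00352). The distal calls of the Pax, ephrin and Eph, and netrin, Slit and Robo families and the promoter calls of the ephrin and Eph and the semaphorin families were not made in either replicate alone, nor was the distal call of the UDP glucuronosyltransferase family, and that of cytochrome P450 was not made in replicate 2.

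Wnt genes had few open promoters and many distal regions in the conservative list. Of 19 Wnt genes 4 had an open promoter (adjusted p = 0.00562, Fisher's exact test), and the family had 3.37 times the expected number of distal regions (adjusted p = 0.00720; 4.51 and 3.92 in the replicates). Of 14 NK homeobox genes 2 had an open promoter (adjusted exact p = 0.00526). In the less strict replicated list 68.4% of the Wnt and 57.1% of the NK homeobox promoters were open, and neither family was called (adjusted exact p = 0.852 and 0.732). Clustered protocadherin genes had 4 of 56 open and delta protocadherin genes 11 of 12, but the delta call (adjusted exact p = 0.0400) was made neither in a replicate nor in the replicated list. Zinc finger protein genes, at 303 of 365, ribosomal protein genes, at 75 of 79, and histone genes, at 61 of 67, were mostly open. Histone genes had 4.10 times the expected number of distal regions (5.84 and 5.45 in the replicates, 2.72 in the replicated list). The counts were small, with a mean of 0.194 regions per gene against 0.0474 expected, and 10 of the 67 genes had any. No keratin gene (of 49) or kallikrein gene (of 27) had an open promoter, though 6.12% and 7.41% did in the replicated list.

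At promoter summits the motif content differed from that at distal summits. ETS matches were in 6.82% of promoter windows and 0.559% of distal ones, NFY in 22.3% and 10.4%, and SP/KLF in 19.1% and 3.52%. CTCF was in 0.995% and 5.22%, the HOX-PBX site in 0.412% and 3.54%, and the TAAT homeodomain site in 0.792% and 6.35%. Base composition was not matched in these shares. Chromosome X had 3.92 regions per Mb and 1.37 distal regions per Mb, and the autosome with the fewest, chromosome 14, had 7.27 and 3.77.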
